A study of Mus musculus with 6 samples.

How the data were processed

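RNA from bone-marrow neutrophils of mice was profiled on Affymetrix expression arrays, with 3 arrays for miR-223 null animals and 3 for wild-type animals. miR-223 is a microRNA, a short RNA that lowers the stability and translation of transcripts that pair with it, and it is abundant in the myeloid lineage. Per the labels' protocols, the cells were taken with a Gr-1 antibody on magnetic columns, the RNA was extracted with Tri Reagent and RNeasy Plus, and it was labelled with biotin by the Affymetrix standard procedure. The Gr-1 antibody binds Ly6G on neutrophils and also Ly6C, which monocytes carry.

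The values analysed were the log2 expression values that the authors deposited, 1 per probe set and array, for 45101 probe sets. A probe set is a group of short probes against a transcript, and several probe sets can measure the same gene. Per the submitters' processing notes the software GCOS was used. Its version and the steps of background correction, normalization and summary are not given in the sources used here. The log2 scale was inferred from the deposited values, which ran from 2.12 to 14.98. After sorting, the columns of the 6 arrays differed by at most 0.0890 at any rank, so the deposited values were already normalized between arrays and no further scaling was applied. Detection calls and scanner intensities were not used here, so no probe set was classed as detected or not detected. For orientation, the control probe sets for the bacterial trpn gene, which the standard Affymetrix spike-in mixes leave out, lay between 2.57 and 3.14.

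The table identifies each row by a probe set number and does not pair it with a gene. The reference table at hand lists genes and RefSeq accessions but not these probe sets. No probe set was therefore given a gene name, with the exception of control probe sets whose identifier contains the name. For the same reason the planned tests of gene lists (published miR-223 targets, granule, cell cycle, interferon and other pathways, and markers of other cell types), of the miR-223 gene itself, and of target sites in 3′ untranslated regions were not made, and neither were the settings that choose or average probe sets per gene. Loss of miR-223 in the null arrays was not checked. The planned floor was for linear values and was not needed.

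The 64 control probe sets were left out of the test. Of the other 45037 probe sets, those with a mean over the 6 arrays at or above the median of these means (4.83) were tested, which left 22519. In place of 1 probe set per gene, every probe set was tested on its own. The difference, null minus wild type, was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, no covariate), and p-values were adjusted by Benjamini-Hochberg over the 22519 probe sets, with a threshold of 0.05. Figures were drawn with matplotlib 3.10.9. The labels do not say whether the 3 samples of a group came from separate animals, so the p-values measure the spread between these samples, part of which may be technical. The number of arrays limits the precision: the median standard error of a log2 change was 0.128.

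The fit was tested on simulated data with the real means and spreads of the 22519 probe sets and 200 changed ones. The noise was drawn independently for each probe set and array, whereas many real probe sets deviate together. The false calls given here therefore do not measure the error rate in the real data. It recovered 11.9% of changes of 0.5 log2 units, 67.2% of changes of 1 log2 unit and 90.9% of changes of 2 log2 units, with 6 false calls among 119. On a separate simulation with an added shift between the technical sets, the fit with the set as a block recovered 5.97%, 56.7% and 87.9%, with 0 false calls among 100.

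The rule for named items was set before the data were examined: the largest changes in each direction among probe sets past the threshold whose 3 null values lie all above or all below the 3 wild-type values. The rule takes 10 per direction. Because these probe sets have no gene names, the text gives 2 per direction and the range of the rest. Two-sided exact permutation tests were used for single control probe sets, for which the smallest p with 3 arrays against 3 is 0.1.

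Replicates 1 to 3 carry the same numbers in both groups. Deviations from the group means correlated at 0.211 for the arrays numbered 1, −0.124 for those numbered 2 and 0.371 for those numbered 3. Arrays numbered 1 lay in the same technical set, as did those numbered 3, while those numbered 2 did not. The correlations therefore cannot decide on a pairing, and the numbers were not taken to pair the samples. The arrays were also split into 2 technical sets at the largest gap in the mean of the 18 hybridization control probe sets, and this set was used as a block. That alternative, the set block with no filter and with each array left out, an offset of 16 on the linear scale, and averaging null replicates 1 and 2 were chosen after seeing the data. All other alternatives were fixed before the data were examined: quantile normalization, no filter or a filter at the 70th percentile (6.53), leaving out probe sets with the suffixes _S_AT and _X_AT, no intensity trend, array weights, a replicate block, and leaving out each array in turn. The alternative of using the values as deposited is the analysis itself.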

Results

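Transcript levels were compared between neutrophils of miR-223 null mice and of wild-type mice, in 3 arrays per group, to ask how the profile of neutrophil transcripts differs when this microRNA is missing. The arrays had similar distributions, with medians between 4.81 and 4.84 on the log2 scale. Over the 22519 tested probe sets, the SD of the difference between 2 arrays ranged from 0.228 to 0.370 within a group and from 0.354 to 0.491 between groups. The closest pair was null replicates 1 and 2, at 0.228. The first principal component held 41.0% of the variance and placed the 3 null arrays (15.1 to 30.9) apart from the 3 wild-type arrays (−33.9 to −12.3).

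Transcript levels differed between null and wild-type neutrophils for 864 probe sets, mostly by small amounts and, in the fit without a block, more often upward than downward. At an adjusted p of 0.05 (limma, Benjamini-Hochberg), 864 of 22519 probe sets (3.84%) differed, of which 625 were higher in null cells and 239 were lower, a share of 72.3% higher. With a technical set of arrays, described further on, as a block in the fit, 1255 were higher and 1211 lower, a share of 50.9%. In the fit without it, the changes were mostly below 2-fold. The median change was 1.65-fold among the probe sets that rose and 1.58-fold among those that fell. Of the rises, 440 were at least 1.5-fold, 124 at least 2-fold and 5 at least 4-fold. Of the falls, 142 were at least 1.5-fold, 51 at least 2-fold and 1 at least 4-fold. At an unadjusted p under 0.05, 4215 probe sets differed. In all 864 probe sets the 3 null values lay entirely on one side of the 3 wild-type values. Over all tested probe sets, 2885 were separated upward and 2663 downward, together 24.6%. The mean share over all splits of the arrays into 3 and 3 is 10%. Probe sets vary together, so a split unrelated to the groups can also exceed 10%, and the shares of the other splits were not computed.

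The count fell when any single array was left out, and fewer arrays also widen the error. Without null replicate 1 it was 85, without null replicate 2 it was 147, and without null replicate 3 it was 337. Without wild-type replicate 1 it was 592, without wild-type replicate 2 it was 503 and without wild-type replicate 3 it was 410. When null replicates 1 and 2 were averaged and counted as 1 sample, 119 probe sets passed, 102 higher and 17 lower.

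**Figure D1:**
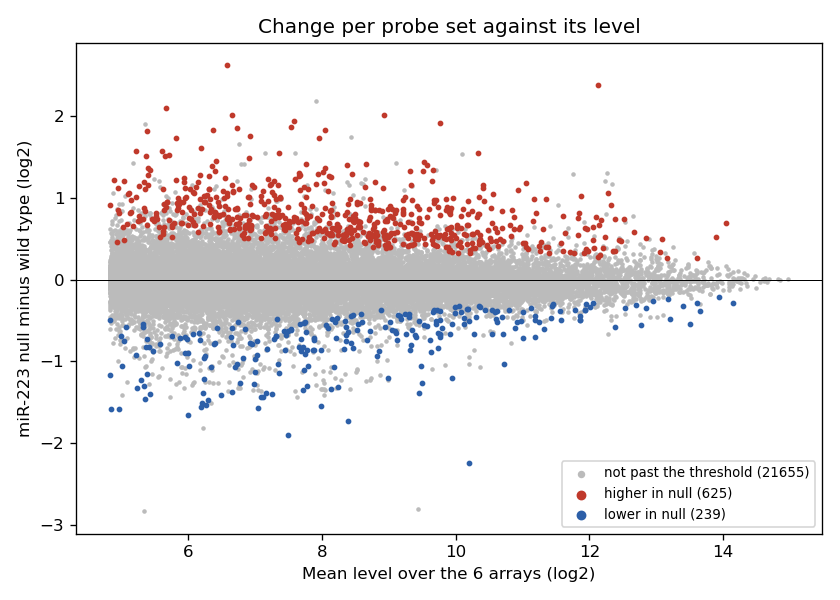
Each point is 1 of the 22519 tested probe sets, with its mean log2 level over the 6 arrays on the horizontal axis and its log2 change, miR-223 null minus wild type, on the vertical axis. The 625 probe sets past the threshold that were higher in null cells (red) and the 239 that were lower (blue) spread over the whole range of levels, and the changes narrow toward the brightest probe sets.

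Changed probe sets were found at all levels of expression and were most frequent among bright ones. The tested probe sets were divided by mean log2 level into 4 bins of 5629 or 5630. In the dimmest bin (4.83 to 5.77), 58 were higher and 23 lower, or 1.44% of the bin. The next bin had 131 higher and 44 lower (3.11%), and the one above it had 208 higher and 66 lower (4.87%). In the brightest bin (8.97 to 14.97), 228 were higher and 106 lower, or 5.93%. The median SD within groups was 0.173 in the dimmest bin and 0.112 in the brightest. Rises outnumbered falls in each bin in the fit without a block. Among probe sets with the suffix _S_AT or _X_AT, which Affymetrix gives to probe sets that can detect more than a single gene, 71 of 1435 and 59 of 1497 passed the threshold, against 619 of 16427 with the plain suffix _AT.

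The largest rise was in probe set 1419561_AT, from 5.27 ± 0.599 in wild-type cells to 7.89 ± 0.583 in null cells (log2, SD, n = 3 each). Its log2 change was 2.63 with a standard error of 0.364, which is 6.18-fold (limma adjusted p = 0.0143). Probe set 1436530_AT rose from 10.9 ± 0.840 to 13.3 ± 0.198 (SD, n = 3 each), a log2 change of 2.38 with a standard error of 0.365 or 5.22-fold (limma adjusted p = 0.0189). The wild-type arrays differed among themselves for this probe set, with values of 10.05, 11.1 and 11.7, and all lay below the lowest null value of 13.2. The largest fall was in probe set 1452732_AT, from 11.3 ± 0.326 in wild-type to 9.07 ± 0.104 in null cells (SD, n = 3 each). Its log2 change was −2.24 with a standard error of 0.157, so that wild-type cells were 4.74-fold higher (limma adjusted p = 0.00192). Probe set 1427878_AT fell from 8.44 ± 0.231 to 6.55 ± 0.0526 (SD, n = 3 each), a log2 change of −1.90 with a standard error of 0.135, or 3.72-fold higher in wild-type cells (limma adjusted p = 0.00192). The 10 largest rises lay between 1.84 and 2.63 on the log2 scale and the 10 largest falls between −2.24 and −1.54.

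Leaving out 1 array ended the call of 1419561_AT once in the fit without a block, without null replicate 1 (log2 change 2.55, limma adjusted p = 0.0816). With null replicates 1 and 2 averaged its change was 2.75 (limma adjusted p = 0.0501), and with the technical set as a block and wild-type replicate 1 left out it was 2.94 (limma adjusted p = 0.0602). The call of 1436530_AT ended without null replicate 1, 2 or 3, at log2 changes of 2.45, 2.27 and 2.43 (limma adjusted p = 0.0884, 0.0913 and 0.0511), and with null replicates 1 and 2 averaged, at 2.36 (limma adjusted p = 0.0886). The probe sets 1452732_AT and 1427878_AT stayed past the threshold in each of these fits.

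**Figure D2:**
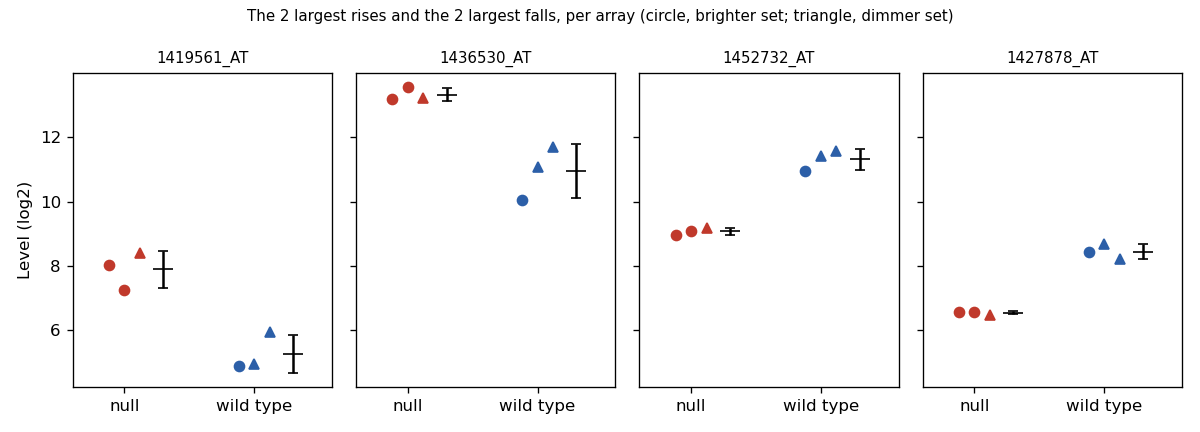
Log2 level of the 2 probe sets with the largest rise and the 2 with the largest fall, per array, in miR-223 null (red) and wild-type (blue) neutrophils, with the mean and SD of the 3 arrays as a black bar. Circles are arrays of the technical set with brighter hybridization controls and triangles those of the dimmer set. In each panel the 3 null values lie apart from the 3 wild-type values.

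The arrays also parted along a technical line that cut across the groups. It did so unevenly, with more null than wild-type arrays on the brighter side. The fit without a block therefore carries part of any difference between the sets. The hybridization controls are bacterial and phage sequences (BioB, BioC, BioD and Cre) that Affymetrix protocols add after labelling. Their mean over 18 probe sets was 10.94 on null replicates 1 and 2 and 10.98 on wild-type replicate 1. It was 10.77 on null replicate 3, 10.72 on wild-type replicate 2 and 10.81 on wild-type replicate 3. The sets were defined by the largest gap between neighbouring arrays, which was 0.131. The next gap was 0.0501. The second principal component, with 25.8% of the variance, separated the same 2 sets, at 15.98 to 19.98 for the brighter set and −21.1 to −15.2 for the dimmer set. The log2 difference between the 3′ and 5′ probe sets followed the same line. For the dap control, a bacterial transcript added to the RNA before labelling, it was 2.13 to 2.34 on the brighter arrays and 1.78 to 1.96 on the dimmer ones. For Gapdh it was 0.230 to 0.335 and 0.0379 to 0.172.

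**Figure D3:**
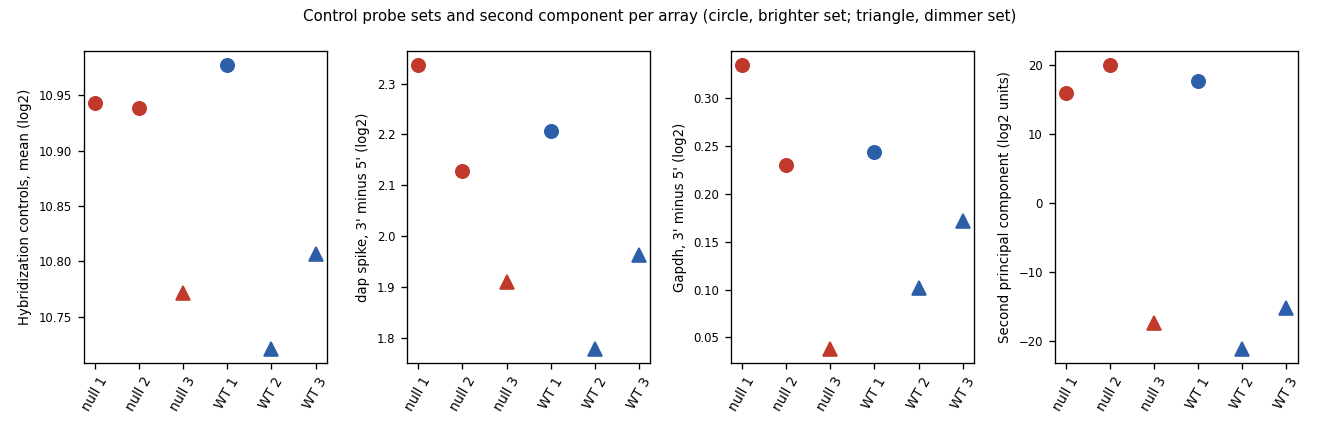
Mean log2 level of 18 hybridization controls, log2 difference between 3′ and 5′ probe sets of the dap spike and of Gapdh, and second principal component, for each of the 6 arrays (red, miR-223 null; blue, wild type; circle, brighter set; triangle, dimmer set). In each panel null 1, null 2 and wild type 1 lie above the other arrays, in the first panel by the definition of the sets. The sign of the component is arbitrary and was chosen so that the brighter set lies above. The lys spike, not shown, did not part the sets.

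Within the sets the comparison of null and wild type was repeated on separate arrays. In the brighter set, the mean of null replicates 1 and 2 was set against wild-type replicate 1, and in the dimmer set null replicate 3 against the mean of wild-type replicates 2 and 3. The 2 sets of changes share no array and correlated across probe sets with Pearson's r = 0.586 and Spearman's rho = 0.501. Probe sets are not independent replicates, so no p is given. Of all tested probe sets, 66.7% changed in the same direction in both sets. The rise of 1419561_AT was 2.74 in the brighter set and 2.94 in the dimmer one. For 1436530_AT it was 3.33 and 1.84. The fall of 1452732_AT was −1.93 and −2.33, and that of 1427878_AT was −1.87 and −1.95, in log2 units.

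With the set as a block in the fit, 2466 probe sets passed the threshold, among them all 864 of the fit without it, and the directions were nearly balanced. Of these, 1255 were higher and 1211 lower in null cells, a share of 50.9% higher against 72.3% without the block. Of these calls, 629 rises and 515 falls were at least 1.5-fold, 144 and 184 at least 2-fold, and 5 and 3 at least 4-fold. Without wild-type replicate 1, the lone wild-type array of the brighter set, the block fit had 123 calls, of which 76.4% were higher, and without null replicate 3 it had 464. Either omission leaves a single set in which null and wild type are compared. The set itself had an effect past the threshold on 436 probe sets, of which 5 were among the 864. A set effect widens the error of the fit without a block, which keeps such probe sets from being called there. The small overlap is therefore no evidence that the calls are free of the sets.

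**Figure D4:**
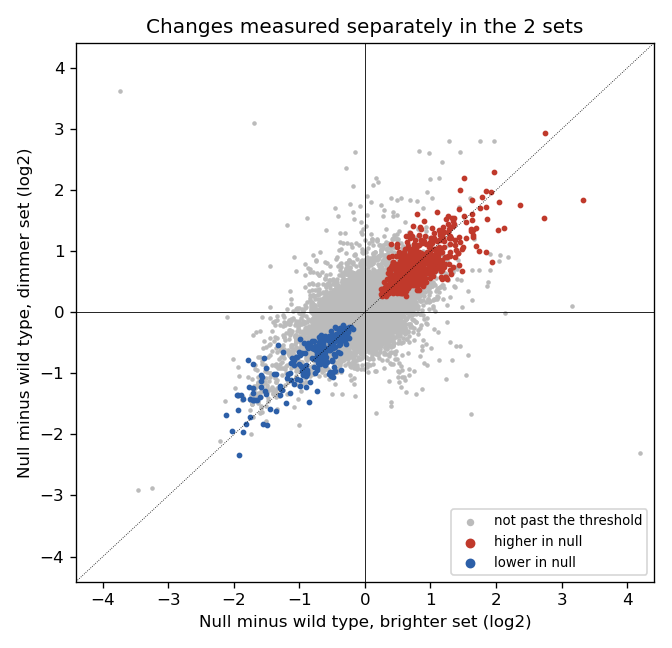
Log2 change, miR-223 null minus wild type, of each tested probe set in the brighter technical set (horizontal axis, 2 null arrays against 1 wild-type array) and in the dimmer set (vertical axis, 1 null array against 2 wild-type arrays). Red and blue points are the 625 and 239 probe sets past the threshold over all 6 arrays, which lie on the same side of 0 in both sets by construction, since their groups do not overlap. The dotted line marks equal changes, and r over all points is 0.586.

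Of the transcripts that the control probe sets name, Gapdh, a glycolytic enzyme, lay lower on all null arrays for 2 of its 3 probe sets, with the smallest exact permutation p that 3 arrays against 3 allow, and the values of beta-actin, a protein of the cytoskeleton, overlapped between the groups. The 3′ Gapdh probe set lay at 13.99 ± 0.00743 in null and 14.09 ± 0.0272 in wild-type cells (SD, n = 3 each), a difference of −0.0998, with all 3 null values below the wild-type values (two-sided exact permutation p = 0.1, the smallest this design allows). The middle Gapdh probe set differed by −0.0958 in the same way, and the 5′ one by −0.128 with overlapping values (exact permutation p = 0.3). The 3′ beta-actin probe set differed by 0.00283 (exact permutation p = 0.9). Its mean was 14.73 in both groups, near the highest value of any probe set (14.98), so the small difference says little about the transcript. The 3′ probe set for the transferrin receptor, which takes up iron and is abundant on red cell precursors, was at 4.02 ± 0.214 in null and 4.25 ± 0.134 in wild-type cells (SD, n = 3 each, exact permutation p = 0.3). Both means lay below the filter of 4.83 that tested probe sets had to reach, so they say little about the transcript. The 3′ probe set for pyruvate carboxylase was at 5.97 ± 0.0982 and 6.07 ± 0.0423 (SD, n = 3 each; exact permutation p = 0.3). The 3 probe sets for 18S ribosomal RNA overlapped between the groups and followed the technical sets, with the 3′ one at 9.07 to 9.97 on the brighter arrays and 8.50 to 8.80 on the dimmer ones, the middle one at 8.35 to 9.02 and 7.61 to 7.87, and the 5′ one at 9.87 to 10.67 and 9.005 to 9.54. Among the other mouse transcripts, 2 of 3 probe sets for beta-actin, 1 of 3 for Gapdh and 1 of 3 for the transferrin receptor were lower on every brighter array, and 2 of 3 for B1 and B2 repeats were higher. Of the 64 control probe sets, 2 had all null values below the wild-type values and 0 had them all above. The mean share over all splits into 3 and 3 is 10% for both directions together. Control probe sets vary together, so 10% is not a chance level for a single split.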

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

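The tests of the technical sets, of the excess of rises, of the 2 closest null arrays and of other splits of the arrays were chosen only after the results were seen. Among the 22518 dimmer probe sets that were left out of the main test, 47 passed the threshold when all probe sets were fitted together (limma), 36 of them higher and 11 lower in null cells. With the technical set as a block in that fit, 124 of the dimmer probe sets passed, 72 higher and 52 lower. In groups of 3 arrays no test for single outlying arrays was made.

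The 6 arrays parted into a brighter set (null replicates 1 and 2, wild-type replicate 1) and a dimmer set (null replicate 3, wild-type replicates 2 and 3) by their hybridization controls. The poly-A controls, bacterial transcripts that are added to the RNA before labelling, parted the same way: the difference between 3′ and 5′ probe sets was higher on every brighter array for 3 of 4 such transcripts (dap, phe and thr, not lys), each measured by 2 families of probe sets. Thus 6 of 8 differences parted the sets. No other split of the arrays into 3 and 3 was followed by more than 1. But each difference follows exactly 1 such split, so few were left for the others, and their low number adds no support. Quality of the neutrophil RNA alone is argued against, since the dap control comes from outside the cells and its lowest brighter-set value still exceeded the highest dimmer-set value by 0.165. Labelling or hybridization in 2 rounds may account for the sets, but the labels name no round, and all 3 probe sets for 18S ribosomal RNA, which comes from the cells, were also higher on every brighter array, so a difference between the RNA samples or the mice of the sets, which was not tested, stays open beside it.

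The technical sets are argued against as the cause of the difference between null and wild type, because each set holds both groups and the changes measured in them separately correlated at 0.586. Of the 9 ways to pick the lone array in each set, the other 8 gave −0.433 to 0.320. Each of these 8 puts null and wild-type arrays together in a set and so carries part of the real difference, with either sign. They are therefore no baseline for the 0.586. Of the 10 splits of the 6 arrays into 3 and 3, only the real split, 1 of 10, gave as many as 864 probe sets, and the highest of the others gave 2. The split that follows the technical sets gave 0 calls, with 2595 probe sets at an unadjusted p under 0.05. Every split but the real one leaves the difference between null and wild type in the error, which holds its count down. With null and wild type also in the fit, the technical set had an effect past the threshold on 436 probe sets. With 10 splits a share under 0.05 cannot be reached.

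The excess of rises among the 864 probe sets, 72.3%, fell to 50.9% with the technical set as a block. Without wild-type replicate 1 it was 76.4% of 123 calls, but that fit compares only null replicate 3 with wild-type replicates 2 and 3. Among all tested probe sets that differed at least 1.5-fold, whatever their p, 755 were higher and 494 lower; 58.3% of these rises and 28.7% of these falls passed the threshold, and 78.1% and 82.2% with the block. In the fit without a block, these falls and rises had a similar median size (0.80 and 0.77 log2 units), but the falls spread wider. Their median SD within groups was 0.355 against 0.214, and their median standard error 0.229 against 0.157. The median size of the change over its standard error was 3.87 against 5.12. The larger error goes with the lower share of falls that passed. With the block the falls still spread wider (SD 0.267 against 0.176, standard error 0.180 against 0.141) while passing slightly more often. Their median change grew to 0.92 log2 units (0.79 for the rises), and that ratio to 5.596 (5.434 for the rises). Whether the spread accounts for the whole excess stays open, since more rises than falls were at least 1.5-fold whatever their p. A shift between arrays that many falls share stays open as well. After each probe set was scaled, 58.4% of their variance within groups lay on a single component. It was at most 52.6% in 1000 random lists of the same size drawn to match their level and spread (median SD 0.337). But the 38.6% of the rises lay below all 1000 of their own lists (median 43.7%). Random lists are therefore no fair comparison for probe sets chosen by their change. The mean deviation of the falls from their group means did follow the technical sets. On the brighter arrays it was 0.032 (null 1), 0.115 (null 2) and 0.302 (wild-type 1). On the dimmer ones it was −0.147 (null 3), −0.260 (wild-type 2) and −0.042 (wild-type 3). The rises did not split this way. Still open is a rise of transcripts that miR-223 holds down, since without gene names target sites could not be assigned. With the block, 54.4% of the probe sets that differed at least 1.5-fold were higher. When each array was left out the share ranged from 48.7% (without null replicate 3) to 59.4% (without wild-type replicate 1). Both of these fits compare the groups in a single technical set.

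Null replicates 1 and 2 lay closer to each other (SD of the difference 0.228) than any other pair of arrays, and counting them as 1 sample left 119 of the calls. A single RNA extract on 2 arrays stays open. The largest difference between them was 7.23 log2 units and the next 5.83, and 8 probe sets differed by over 2, which goes against it. But these are the extremes of all probe sets, looked at after their values were seen. Whether a fault of an array at these probe sets gave them was not tested. Handling in the same technical set stays open, since the other pair that shares a group and a set, wild-type replicates 2 and 3, was only slightly closer (0.318) than the closest pair of a group from different sets (0.323). Whether the 2 samples came from litter mates or from pooled animals was not tested.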

How the results depend on the processing

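The set block with and without the filter, the offset, the averaging of null replicates 1 and 2 and the tests of the set block without single arrays were chosen after seeing the data. The count stayed within 1.5 times of 864 with quantile normalization (880), no filter (700), a filter at the 70th percentile (837), without _S_AT and _X_AT probe sets (760), without the intensity trend (607), with array weights (1238), with the offset (863) and with the replicate block. Falls moved by more than 1.5 times without the trend (131) and with array weights (367). The replicate block gave 857 calls (618 higher, 239 lower), of which 671 were among the 864. The correlations of same-numbered arrays went with the technical sets and could not decide on a pairing. Of the 6 arrays, 3 correlated best with their own number. Leaving out 1 array gave 85 to 592 calls, 73 to 478 higher, 12 to 194 lower, and a share of 61.4% to 85.9% higher; fewer arrays widen the error. Null replicates 1 and 2 counted as 1 sample gave 119 calls, 102 higher and 17 lower (85.7% higher). The set block gave 2466 calls, 1255 higher and 1211 lower (50.9% higher), and without the filter on dim probe sets 2098, 1115 higher and 983 lower (53.1% higher). With the set block and 1 array left out, calls ranged from 123 to 2909, rises from 94 to 1425, falls from 29 to 1484 and the share of rises from 49.0% to 76.4%. Without null replicates 1, 2 and 3 in turn these block fits gave 928, 891 and 464 calls, with 399, 397 and 175 falls, 289 rises without null replicate 3, and shares of 57.0%, 55.4% and 62.3% higher. Without wild-type replicates 1, 2 and 3 they gave 123, 2909 and 2418 calls, 94, 1425 and 1257 rises, 29, 1484 and 1161 falls, and for replicates 2 and 3 shares of 49.0% and 52.0%. The block fits without null replicate 3 or without wild-type replicate 1 compare the groups in a single technical set. Why the block raises the count in the real data was tested only as far as the spread and size of rises and falls given above. The separate simulations (100 calls with the block, 119 without) do not bear on this. They used different simulated values, a shift was added only for the block, and their noise had the spread of the fit without a block. The 4 named probe sets kept their call in 85 of 92 fits; their direction could not turn in fits on fewer or averaged arrays, since their groups do not overlap. Log2 changes ranged from 2.21 to 3.05 for 1419561_AT and from 1.84 to 3.33 for 1436530_AT. They ranged from −2.43 to −1.93 for 1452732_AT and from −2.01 to −1.73 for 1427878_AT. Quantile normalization moved the median change by −0.00346. Signal over background was not known, so no limit from it is given.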

Other observations

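A few probe sets varied widely within a group; they were picked on that range after their values were seen. Over all probe sets outside the controls, 86 had a range of over 2 log2 units within a group, 12 of over 3 and 4 of over 4. Probe set 1427451_A_AT was at 10.6 on null replicate 1 and between 3.34 and 4.04 on the other 5 arrays. Probe set 1422318_AT was at 3.11 on null replicate 1 and 3.28 on wild-type replicate 2, and between 7.72 and 8.99 on the other 4. Among the 86, null replicate 3 was the highest array in 40, wild-type replicate 2 the lowest in 44, and both held for 31. Over all probe sets, null replicate 3 was the highest array in 17.0%, wild-type replicate 2 the lowest in 15.5%, and both held in 3.29%. The genes behind these probe sets were not named here.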
